A study of Homo sapiens with 8 samples.

How the data were processed

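Polyadenylated RNA from 92.1 uveal melanoma cells was sequenced by the submitters in 8 libraries, 2 for each of DMSO and 100 nM FR900359 at day 1 and day 3. Groups and experiment numbers were taken from the sample titles, and the series design states 2 independent experiments. The deposited values are log2 values per gene and library. From the values, the authors had taken log2 of CPM after adding 0.5 read to each gene, relative to total reads times a scaling factor between 0.921 and 1.08. STAR, edgeR and the genome build hg19 are named per the submitters' processing notes; their versions and roles, the counting tool, the annotation release and the handling of strand are not given in the sources used here.

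Each library's values step by whole reads, so that 100% of values gave a whole number of reads within 0.01. Total reads per library came to between 25685164 and 35336967. The tables list 36441 genes with symbols and Ensembl identifiers, after 527 repeated entries with identical values were dropped, and each listed gene has a read in some library. A gene was tested if it had at least 0.336 CPM, or 10 reads in the median library, in at least 2 libraries and at least 15 reads in all. This left 17288 genes (13486 protein coding) with 99.9% of reads.

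The plan made before the data were examined set a count model as the main test and a second count tool as an alternative. The deposited unit is log2, and neither was run; the whole reads recovered from the values were tested with limma-voom as an alternative. The main test was limma-trend (limma 3.58.1 in R 4.3.3, lmFit and eBayes with trend and robust settings) on the deposited log2 values, with 4 group means and all 8 libraries, which leaves 4 residual degrees of freedom and a median of 16.4 prior degrees of freedom. Contrasts were FR900359 against DMSO at each day, the difference between these, and DMSO at day 3 against day 1. A gene was called at Benjamini-Hochberg adjusted p under 0.05. The tests are two-sided.

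On simulated reads drawn for 17288 genes from the real means and library sizes, with 200 genes changed, the procedure recovered 55.2% of 1.5-fold, 74.6% of 2-fold and 89.4% of 4-fold changes at day 1, with 8.18% of calls false. At day 3 it recovered 61.2%, 73.1% and 89.4% with 12.9% false, for the difference between the days 65.7%, 64.2% and 86.4% with 7.69% false, and for DMSO over time 64.2%, 80.6% and 95.5% with 8.05% false. False shares were thus above the nominal 5% in these simulations. Far fewer genes were changed in them than were called in the real data, so these rates need not hold there. The median SE of a log2 fold change in the real data was 0.089, and 0.126 for the difference between the days. The p-values rest on 1 spread per gene, pooled over the 4 groups and moderated with that of other genes. They cover only the experiments of this series. At a mean log2 CPM of at least 3, the SD of the difference between replicates was 0.126 in DMSO day 1. It was 0.0802 to 0.0880 in the other groups, so the pooled spread may be too small for contrasts with DMSO day 1.

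Replicates were compared before use. The chi-square of reads per degree of freedom between the libraries of a group was 9.61 in DMSO day 1, 2.82 in DMSO day 3, 2.40 in FR900359 day 1 and 2.19 in FR900359 day 3, so each pair differed by more than sampling noise. The experiment number pairs libraries by the titles and the series design. Deviations from group means of libraries with the same number correlated across genes between -0.137 (DMSO day 1 with FR900359 day 1) and 0.0348, and the experiment number was added as a block in an alternative fit. The libraries carry no other batch label.

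29 gene lists were fixed before the data were examined: pigment and melanocyte differentiation, neural crest and invasive melanoma, DNA replication, mitosis, ERK pathway output, YAP and TAZ targets, Gq signalling components, PRC2 subunits, HOX, a uveal melanoma prognosis panel, BCL2 family, p53 targets, lysosome, cholesterol synthesis, glycolysis, oxidative phosphorylation, ribosome biogenesis, cytosolic ribosomal proteins, unfolded protein and amino acid stress, interferon response, NF-kB, cAMP and CREB targets, matrix and adhesion, replication-dependent histones, mitochondrially encoded genes, and fibroblast, leukocyte, epithelial and endothelial markers. The 27 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which asks only whether a list's genes move one way on balance. None of the camera calls held with an estimated correlation. That version takes the correlation and its test from the 4 residual degrees of freedom, so it has little power. Its failures leave a call open. The correlations it estimated at day 1 included 0.47 for cholesterol synthesis, 0.226 for DNA replication and 0.229 for mitosis genes. Those for neural crest (-0.00202) and Gq genes (-0.00361) lay below the preset 0.01. Where the true correlation exceeds the preset, the camera adjusted p is too small.

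Genes were named by a rule set before the data were examined: at each day the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 3 and the same direction in both experiments, leaving out unnamed clones; the 5 largest each way for the difference between the days and for DMSO over time; up to 4 members of each list with the largest absolute change at day 3 and a mean log2 CPM of at least 1, of which the text gives some; and GNAQ, GNA11, MITF, EZH2, CCND1, MYC, CDKN1A and CDKN1B. Some genes picked by this rule are not reported here. Ratios of summed reads carry exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. Transcript lengths and GC content came from GENCODE release 29, matched by Ensembl identifier to 99.1% of tested genes. That annotation is of another build than hg19, so no coordinates are given.

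Alternatives were RLE, upper-quartile and total-count scaling, no low-count filter, a stricter one, the replicate block, limma-voom on the whole reads, fits on the compared groups alone, an added 2-fold threshold and leaving out each library in turn. Crossed experiment numbers, and fits with a trend of length or GC content removed, were added after seeing the data, as were contrasts of FR900359 at day 3 with either group at day 1 and list tests in DMSO over time under the other scalings.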

Results

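Polyadenylated RNA was sequenced from 92.1 cells, an established human uveal melanoma line that carries an activating mutation of GNAQ, the gene of a Gq-class G protein alpha subunit. The cells received FR900359, a cyclic depsipeptide that inhibits Gq-class alpha subunits, at 100 nM or the DMSO vehicle, and were collected after 1 day or 3 days. The 8 libraries formed 4 groups of 2, with 1 library of each group from each of 2 independent experiments. The total was 32207151 and 28598631 reads in the DMSO day 1 libraries and 29348184 and 30684798 in DMSO day 3. It was 25685164 and 35166189 in FR900359 day 1, and 29740298 and 35336967 in FR900359 day 3. Between 11.4% and 13.7% of reads came from mitochondrially encoded genes. At least 1 read was found for 27379 and 28234 genes in DMSO day 1, 25668 and 25701 in DMSO day 3, 28330 and 28912 in FR900359 day 1, and 23867 and 24779 in FR900359 day 3.

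The libraries separated by group in principal components of the 9758 genes with a mean log2 CPM of at least 3. The first principal component held 60.2% of the variance and set the FR900359 day 3 libraries (44.4 and 43.7) apart from all others (-26.4 to -3.66). The second held 30.9% and set the DMSO day 3 libraries (32.3 and 33.0) apart from the rest (-15.9 to -7.39). Levels are given in CPM, reads scaled to library size, as mean ± SD of the 2 libraries of a group, and log2 fold changes with their standard error (SE), each from 2 libraries against 2. Every adjusted p is from limma with Benjamini-Hochberg adjustment unless a gene list test is named.

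**Figure D1:**
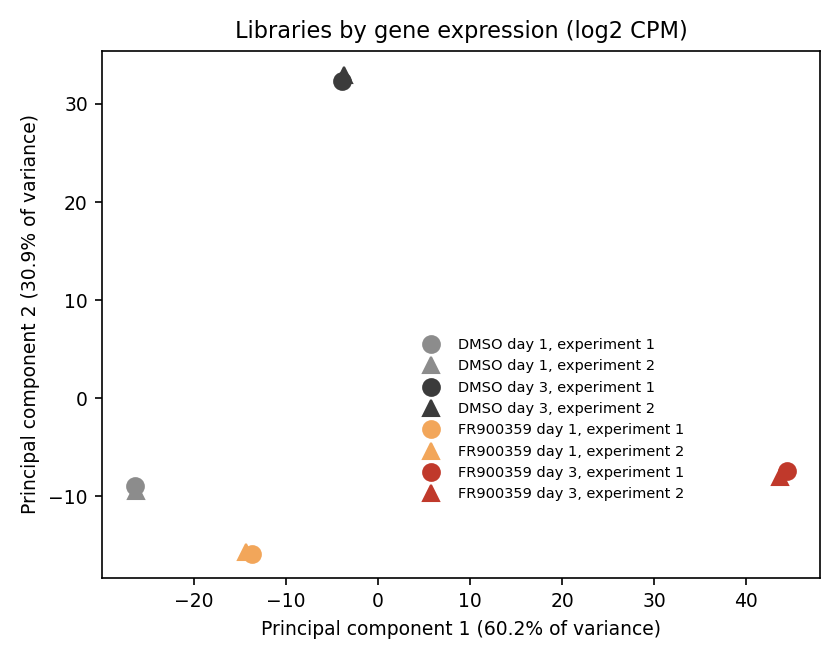
Principal components 1 and 2 of the log2 CPM of 9758 genes with a mean of at least 3, with 1 point per library. Circles show experiment 1, triangles experiment 2 and colours the 4 groups. The libraries of each group lay next to each other, and FR900359 day 3 lay farthest along component 1.

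The first comparison asked how Gq inhibition changed expression after 1 day. EDNRB, the endothelin receptor of melanocyte development, rose from 55.6 ± 4.16 to 215 ± 0.822 CPM (log2 fold change 1.95, SE 0.052, adjusted p = 1.21e-16), and BMF, a pro-apoptotic member of the BCL2 family, from 7.03 ± 0.438 to 32.2 ± 0.0979 CPM (2.19, SE 0.075, adjusted p = 7.40e-15). MXD4, a partner of MAX that opposes MYC, rose from 27.9 ± 0.435 to 79.2 ± 2.22 CPM. Among the genes that fell, ADRA2A, an adrenergic receptor, went from 49.9 ± 0.836 to 5.11 ± 0.599 CPM (log2 fold change -3.29, SE 0.12, adjusted p = 5.56e-14), and WFDC1, a secreted protein with a whey acidic protein domain, from 124 ± 2.85 to 13.2 ± 1.43 CPM (-3.23). NR4A3, an orphan nuclear receptor, fell from 142 ± 9.68 to 30.9 ± 0.483 CPM, and SLC38A1, a glutamine transporter, from 180 ± 2.52 to 52.4 ± 1.59 CPM.

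Among genes with a mean log2 CPM of at least 3, the other genes with the largest rises at day 1 were MYO15B, an unconventional myosin gene (log2 fold change 2.15), PKD1L2 of the polycystin family (1.95), LGI3, a secreted leucine-rich protein (1.67), the lysophospholipase PNPLA7 (1.57), the kinase DYRK1B (1.51), the neuron navigator gene NAV3 (1.5) and the endocytic adaptor STON1 (1.49). At that level the other genes with the largest falls were the neurofilament gene NEFH (-2.88), the CDC42 effector CDC42EP1 (-2.17), TEX15 (-2.15), BAIAP2L2 (-1.87), the immune cell receptor SLAMF7 (-1.80) and the homeobox gene HLX (-1.77). Their adjusted p-values lay between 8.92e-16 and 3.20e-08, and each moved the same way in both experiments, as the naming rule required.

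Cholesterol synthesis genes fell together at day 1. Of 24 tested, 23 were lower and 0 higher, both over all genes and adjusted over the list alone, with a median log2 fold change of -0.67. SQLE, squalene epoxidase, fell from 227 ± 5.20 to 74.7 ± 1.83 CPM (log2 fold change -1.60, SE 0.041), HMGCS1, which makes the precursor of mevalonate, from 97.8 ± 2.36 to 36.3 ± 3.04 CPM (-1.43), and INSIG1, a sterol-regulated retention protein, from 66.9 ± 2.95 to 25.9 ± 0.322 CPM (-1.37). MVD, mevalonate diphosphate decarboxylase, changed by -0.84. The list passed the camera test with adjusted p = 4.30e-18, against adjusted p = 0.259 with an estimated correlation.

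Proliferation genes were lower at day 1. In the DNA replication list 28 of 40 genes fell and 2 rose (29 and 3 adjusted over the list alone). The median was -0.27, with camera adjusted p = 3.03e-08 and adjusted p = 0.295 with an estimated correlation. In the mitosis list 24 of 47 fell and 1 rose, also adjusted over the list alone. The median was -0.18, with camera adjusted p = 2.76e-05 and adjusted p = 0.529 with an estimated correlation. UHRF1, which guides maintenance of DNA methylation, and ANLN, an actin-binding protein of cytokinesis, both had a log2 fold change of -0.24. Ribosome biogenesis genes also fell, 13 of 30 lower and 1 higher (14 and 1 adjusted over the list alone). The median was -0.11, with camera adjusted p = 0.00228 and adjusted p = 0.601 with an estimated correlation.

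Melanocyte and adhesion genes were higher at day 1. In the list of pigment and melanocyte differentiation genes 12 of 27 rose and 4 fell (12 and 5 adjusted over the list alone). The median was 0.13, with camera adjusted p = 2.18e-04 and adjusted p = 0.262 with an estimated correlation. OCA2, a melanosomal transporter, rose from 13.4 ± 1.44 to 26.7 ± 0.255 CPM and MYO5A, a motor of melanosome transport, by 0.41 on the log2 scale, while TYRP1, a melanin synthesis enzyme, fell by 0.23. In the list of matrix and adhesion genes 20 of 40 rose and 5 fell (21 and 5 adjusted over the list alone). The median was 0.23, with camera adjusted p = 3.83e-07 and adjusted p = 0.259 with an estimated correlation. THBS1, thrombospondin, rose from 127 ± 0.365 to 263 ± 34.0 CPM and the matrix glycoprotein TNC from 364 ± 12 to 606 ± 25.2 CPM. In the list of neural crest and invasive melanoma genes 10 of 22 rose and 2 fell (11 and 2 adjusted over the list alone). The median was 0.22, with camera adjusted p = 0.00168 and adjusted p = 0.259 with an estimated correlation. The log2 fold change was 0.71 for the receptor kinase AXL, 0.72 for the nerve growth factor receptor NGFR and 0.42 for the transcription factor SNAI2.

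3 further lists passed the test at day 1. Of 13 genes of the uveal melanoma prognosis panel 6 rose and 2 fell (8 and 2 adjusted over the list alone). The median was 0.21, with camera adjusted p = 0.00228 and adjusted p = 0.259 with an estimated correlation. The chromatin organiser SATB1 had a log2 fold change of 1.39, the axon guidance receptor ROBO1 0.21 and HTR2B, a serotonin receptor of the high-risk class, -1.28. Of 23 YAP and TAZ target genes 12 rose and 3 fell (12 and 4 adjusted over the list alone), with a median of 0.21, camera adjusted p = 0.0202 and adjusted p = 0.295 with an estimated correlation. This call ended without DMSO day 1 replicate 1 (adjusted p = 0.0532) or FR900359 day 1 replicate 2 (adjusted p = 0.0582). Of 29 Gq signalling components 14 fell and 3 rose (15 and 5 adjusted over the list alone), with a median of -0.11, camera adjusted p = 0.0256 and adjusted p = 0.259 with an estimated correlation. The call ended without DMSO day 1 replicate 2 (adjusted p = 0.0849). RASGRP3, an exchange factor that links this pathway to RAS, fell from 103 ± 3.92 to 59.1 ± 2.87 CPM.

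The remaining lists did not pass at day 1. Of 29 ERK pathway output genes 9 were higher and 8 lower (10 and 8 adjusted over the list alone; median 0.11, mean 0.04, camera adjusted p = 0.730). The receptor kinase EPHA2 (log2 fold change -1.30) and the feedback inhibitor SPRY1 (-0.70) were lower, as was the early response gene EGR1 (-0.25), whose call ended without FR900359 day 1 replicate 1 (adjusted p = 0.147). The counts of higher and lower genes, with those adjusted over the list alone in parentheses, were 6 and 7 (6 and 8) of 23 p53 targets, 4 and 5 (5 and 5) of 15 BCL2 family genes, and 3 and 4 (3 and 4) of 11 PRC2 subunits. They were 8 and 6 (8 and 6) of 34 HOX genes, 10 and 16 (10 and 17) of 40 lysosome genes and 4 and 2 (4 and 2) of 21 glycolysis genes. They were 2 and 11 (2 and 11) of 39 oxidative phosphorylation genes, 8 and 1 (8 and 1) of 42 cytosolic ribosomal protein genes, and 4 and 12 (5 and 12) of 26 unfolded protein and amino acid stress genes. Inflammatory and cAMP lists stood at 4 and 2 (4 and 2) of 22 interferon response genes, 0 and 2 (0 and 1) of 10 NF-kB genes and 3 and 6 (3 and 6) of 17 cAMP and CREB targets. The last ones stood at 3 and 3 (2 and 2) of 25 replication-dependent histone genes and 3 and 0 (3 and 0) of 13 mitochondrially encoded genes. Markers of other cell types stood at 1 and 3 (1 and 3) of 6 fibroblast genes, 2 and 0 (2 and 0) of 5 epithelial genes, 0 and 0 (0 and 0) of 3 leukocyte genes and 0 and 1 (0 and 1) of 4 endothelial genes, the last 2 lists being too small for a test. Calls appeared when 1 library was left out: ribosomal protein genes passed upward without DMSO day 1 replicate 1 (adjusted p = 6.75e-05) or FR900359 day 1 replicate 1 (adjusted p = 0.00775), and epithelial genes without FR900359 day 1 replicate 1 (adjusted p = 0.0199) or either FR900359 day 3 library (adjusted p = 0.0494 and 0.0475). Without DMSO day 1 replicate 2, oxidative phosphorylation (adjusted p = 9.36e-05) and amino acid stress genes (adjusted p = 0.00957) passed downward and mitochondrially encoded genes upward (adjusted p = 0.0268). Ribosomal protein genes also passed upward with RLE scaling (adjusted p = 0.0318) and with total-count scaling (adjusted p = 0.0154), as did mitochondrially encoded genes with total-count scaling (adjusted p = 0.0414).

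In limma-trend 5814 of 17288 tested genes differed at day 1 (adjusted p under 0.05), 2291 higher and 3523 lower, of which 224 and 324 by at least 2-fold. The count was 3864 without FR900359 day 1 replicate 1, and scaling by total reads alone gave 2936 higher and 2961 lower. GNAQ itself had a log2 fold change of -0.01 (SE 0.051, adjusted p = 0.868), GNA11, its paralog, -0.23 (adjusted p = 3.15e-04) and MITF, the melanocyte master regulator, -0.05 (adjusted p = 0.419). It was for the cyclin gene CCND1 -0.38 (adjusted p = 1.49e-07), the cell cycle inhibitor CDKN1A -0.93 (adjusted p = 1.50e-10) and its relative CDKN1B -0.06 (adjusted p = 0.526). MITF passed without DMSO day 1 replicate 2 (adjusted p = 0.0358). MYC had 0.12 (adjusted p = 0.0428), a call that ended with the replicate block (adjusted p = 0.0547), without DMSO day 1 replicate 1 (adjusted p = 0.292) or FR900359 day 1 replicate 2 (adjusted p = 0.385), and without any 1 of the day 3 libraries (adjusted p from 0.0602 to 0.0713). The median, the mean and the camera direction did not share a sign at day 1 for PRC2, HOX, glycolysis, interferon, NF-kB and histone genes.

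**Figure D2:**
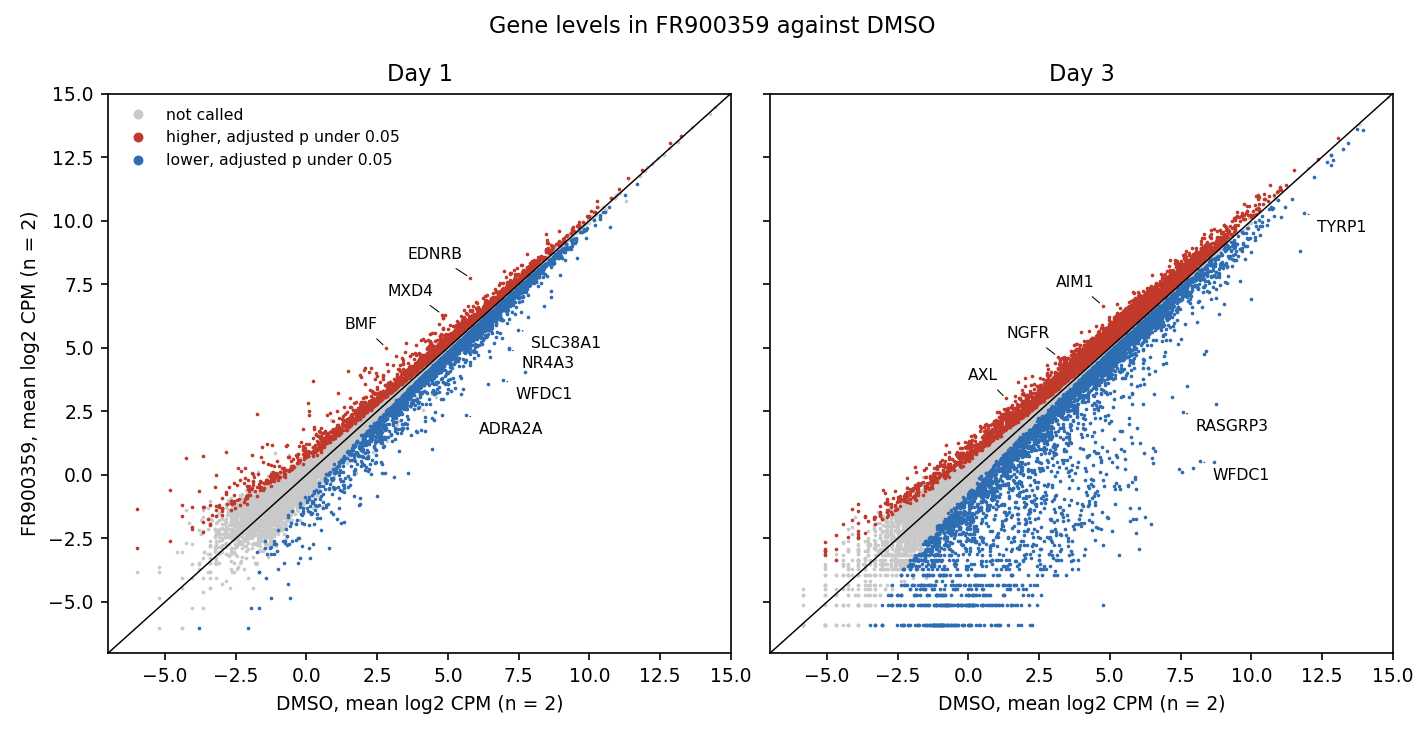
Mean log2 CPM of each of 17288 genes in DMSO (x axis) and FR900359 (y axis) at day 1 (left) and day 3 (right), each a mean of 2 libraries, with the line of equal level. Red and blue points passed adjusted p under 0.05; at day 3 the blue points reached far below the line while the red points stayed close to it.

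The second comparison asked the same after 3 days. Several genes fell from clear expression to under 2 CPM. SLC38A1 went from 248 ± 4.81 CPM in DMSO to 1.23 ± 0.198 in FR900359 (log2 fold change -7.67, SE 0.080, adjusted p = 4.10e-20), ADRA2A from 61.0 ± 0.0357 to 0.304 ± 0.0610 (-7.66, SE 0.12, adjusted p = 3.40e-21). WFDC1 went from 294 ± 5.92 to 1.47 ± 0.196 (-7.65, SE 0.084) and CDC42EP1 from 189 ± 2.10 to 1.09 ± 0.0395 (-7.44, SE 0.065). Rises were smaller. AIM1, a crystallin-domain gene linked to melanoma, went from 26.9 ± 0.272 to 101 ± 0.953 CPM (log2 fold change 1.91, SE 0.052, adjusted p = 7.00e-18), AXL from 2.52 ± 0.105 to 8.03 ± 0.330 (1.67) and NGFR from 9.02 ± 0.521 to 25 ± 1.31 (1.47). In FR900359 at day 3, AXL and NGFR lay below DMSO at day 1 (log2 differences -1.26 and -1.61), while AIM1 lay above it (1.25).

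Among genes with a mean log2 CPM of at least 3, the other genes with the largest falls at day 3 were SOD3, extracellular superoxide dismutase (-7.36), the collagen receptor DDR2 (-7.19), the WNT agonist RSPO4 (-7.02), the glycosyltransferase GBGT1 (-6.48), NEFH (-6.32) and MTSS1, a membrane and actin regulator (-6.09). Among the other genes with the largest rises at that level were the collagenase MMP8 (1.87), the ubiquitin ligase RNF182 (1.53), the matricellular gene NOV (1.45), the taurine transporter SLC6A6 (1.39), THBS1 (1.36) and the netrin gene NTN1 (1.36). All moved the same way in both experiments, as the naming rule required. In FR900359 at day 3, THBS1 (-1.34) and NOV (-0.49) lay below DMSO at day 1, and MMP8 (-0.03) was near that level. SLC6A6 (1.26), RNF182 (0.93) and NTN1 (0.93) lay above it. ADRA2A had 3524 reads in the DMSO day 3 libraries together and 17 in FR900359 day 3, a level 215-fold lower (95% interval from 134 to 370, for counting error only). Fitted fold changes of genes with so few reads depend on the 0.5 read that the deposited values add.

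Proliferation genes were higher with FR900359 at day 3. In the DNA replication list 36 of 40 were up and 1 down (median 0.56, camera adjusted p = 1.95e-10). In the mitosis list 41 of 47 were up and 2 down (median 0.54, camera adjusted p = 9.39e-12). These counts were the same adjusted over the list alone. Both had adjusted p = 0.545 with an estimated correlation. UHRF1 stood at 34.3 ± 1.02 CPM in DMSO and 59.6 ± 1.02 in FR900359, and ANLN at 79.7 ± 5.32 and 146 ± 4.85. In DMSO at day 1 they had been at 99.2 ± 1.19 and 158 ± 1.91 CPM. Glycolysis genes were also higher, 18 of 21 up and 2 down, also adjusted over the list alone. The median was 0.44, with camera adjusted p = 4.73e-05 and adjusted p = 0.545 with an estimated correlation. The pyruvate kinase gene PKM had a log2 fold change of 0.76, while the aldolase gene ALDOC had -5.29. Matrix and adhesion genes were higher in 26 of 40 and lower in 11 (26 and 11 adjusted over the list alone). The median was 0.51, with camera adjusted p = 0.00232 and adjusted p = 0.545 with an estimated correlation. The integrin gene ITGA4 (1.23) and TNC (1.15) were among those that rose. Set against DMSO at day 1, FR900359 at day 3 had 14 glycolysis genes up and 5 down (median 0.25, camera adjusted p = 0.213). On that scale 26 matrix and adhesion genes were up and 9 down (median 0.63, camera adjusted p = 0.00128). With an estimated correlation these lists had adjusted p = 0.833 and 0.620.

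Cytosolic ribosomal protein genes were lower at day 3, 40 of 42 down and 0 up, also adjusted over the list alone. The median was -0.63, with camera adjusted p = 6.03e-18 and adjusted p = 0.545 with an estimated correlation. RPS20 stood at 632 ± 21 CPM in DMSO and 298 ± 15.3 in FR900359, and RPS28 at 17.6 ± 0.217 and 3.48 ± 0.0524. Reads of these genes can be split with near-identical pseudogenes, so single members are uncertain. Unfolded protein and amino acid stress genes were lower in 16 of 26 and higher in 8 (16 and 8 adjusted over the list alone). The median was -0.82, with camera adjusted p = 2.53e-04 and adjusted p = 0.545 with an estimated correlation. CHAC1, a glutathione-degrading enzyme, went from 73.6 ± 3.28 to 1.83 ± 0.0139 CPM and ASNS, asparagine synthetase, from 470 ± 0.108 to 81.0 ± 0.642. DDIT4, an inhibitor of mTOR signalling, had -2.54. Against DMSO at day 1, FR900359 at day 3 had 15 members of this list up and 8 down (median 0.17, camera adjusted p = 0.509). ASNS (1.27) and DDIT4 (0.83) lay above DMSO at day 1, and CHAC1 (-1.78) below it. Target genes of p53 were lower in 12 of 23 and higher in 5 (12 and 6 adjusted over the list alone). The median was -0.30, with camera adjusted p = 0.0421 and adjusted p = 0.545 with an estimated correlation. The log2 fold change of the death receptor gene TNFRSF10B was -5.47, that of CDKN1A -2.51 and that of SESN2, which is also on the amino acid stress list, -2.40. Set against DMSO at day 1, FR900359 at day 3 had 9 p53 targets up and 6 down (median 0.04, camera adjusted p = 0.717). TNFRSF10B (-4.76) and CDKN1A (-1.84) lay below DMSO at day 1, and SESN2 (-0.13) was near it. In DMSO from day 1 to day 3, 13 p53 targets rose and 4 fell (median 0.32, camera adjusted p = 0.0627).

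Members of the pigment list went both ways at day 3, 16 of 27 up and 8 down (16 and 8 adjusted over the list alone; median 0.29, camera adjusted p = 0.287). MYO5A stood at 406 ± 5.55 CPM in DMSO and 817 ± 11 in FR900359, TYRP1 at 3758 ± 14.7 and 1268 ± 27.6, and OCA2 at 12.5 ± 0.695 and 0.508 ± 0.133. Neural crest genes were up in 14 of 22 and down in 5 (16 and 5 adjusted over the list alone; median 0.35, mean -0.11, camera adjusted p = 0.122), with SNAI2 at 0.96. Gq signalling components were up in 15 of 29 and down in 9 (17 and 9 adjusted over the list alone; median 0.13, mean -0.43, camera adjusted p = 0.656), and RASGRP3 went from 190 ± 2.60 to 5.49 ± 0.148 CPM. The prognosis panel had 5 up and 5 down of 13 (6 and 5 adjusted over the list alone; median 0.04, or -0.02 with total-count scaling, mean -0.74, camera adjusted p = 0.859). ROBO1 had 0.73, SATB1 -2.50 and HTR2B -7.05. HTR2B had 757 reads in DMSO and 5 in FR900359, 157-fold lower (95% interval from 67.1 to 486). PRC2 subunits were up in 6 of 11 and down in 1 (6 and 1 adjusted over the list alone; median 0.25, camera adjusted p = 0.103), with the histone methyltransferase gene EZH2 at 0.46 and its partner PHF19 at 0.78.

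Of 34 HOX genes 10 were higher and 13 lower at day 3 (10 and 13 adjusted over the list alone; camera adjusted p = 0.184), with HOXB13 at -5.15 and HOXD1 at -4.68. ERK output genes had 11 up and 10 down of 29 (11 and 12 adjusted over the list alone; camera adjusted p = 0.431), with EPHA2 at -1.78, EGR1 at -1.77 and SPRY1 at -1.10. YAP and TAZ targets had 7 up and 7 down of 23 (7 and 7 adjusted over the list alone; camera adjusted p = 0.934), with MYOF, a membrane repair gene, at 1.10 and the angiomotin gene AMOTL2 at -2.19. Of 15 BCL2 family genes 4 were higher and 10 lower (4 and 11 adjusted over the list alone; median -0.29, camera adjusted p = 0.0529), with the BH3-only gene PMAIP1 at -1.30 and BCL2 at -0.81. The BCL2 family passed the test without any 1 of the 4 day 1 libraries (adjusted p from 0.0407 to 0.0492) and with total-count scaling (adjusted p = 0.0459). Cholesterol synthesis genes had 10 up and 8 down of 24 (10 and 9 adjusted over the list alone; median 0.09, mean -0.01, camera adjusted p = 0.934). SQLE was at -1.30, INSIG1 at 0.39, MVD at 0.45 and HMGCS1 at 0.24, the last not called without FR900359 day 3 replicate 1 (adjusted p = 0.0566).

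The counts up and down in the other lists at day 3, with those adjusted over the list alone in parentheses, were 16 and 7 (16 and 7) of 40 lysosome genes, 12 and 15 (12 and 15) of 39 oxidative phosphorylation genes, 11 and 11 (11 and 11) of 30 ribosome biogenesis genes and 10 and 2 (10 and 2) of 22 interferon response genes. They were 3 and 1 (3 and 1) of 10 NF-kB genes, 7 and 8 (7 and 8) of 17 cAMP and CREB targets, 2 and 10 (1 and 10) of 25 histone genes and 3 and 8 (3 and 8) of 13 mitochondrially encoded genes. The coactivator PPARGC1A had a log2 fold change of 1.01, NR4A3 -2.15 and the mitochondrial gene MT-ND1 -0.51. The histone list passed without DMSO day 3 replicate 1 (adjusted p = 0.0335), and the mitochondrially encoded list without either DMSO day 1 library (adjusted p = 0.0497 and 0.0494) and with total-count scaling (adjusted p = 0.0459). Markers of other cell types stood at 2 and 3 (2 and 3) of 6 fibroblast genes, 0 and 3 (0 and 3) of 5 epithelial genes, 1 and 0 (1 and 0) of 3 leukocyte genes and 1 and 1 (1 and 1) of 4 endothelial genes. Among them FBLN1, a fibulin, had a log2 fold change of -4.15, the splicing regulator ESRP1 -1.25 and EMCN, a sialomucin of endothelium, -7.55.

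In limma-trend 10265 of 17288 genes differed at day 3, 5788 higher and 4477 lower, of which 404 and 1823 by at least 2-fold. The split was 4997 and 5048 with total-count scaling and 6480 and 4005 with upper-quartile scaling, which moved the median of all genes by -0.0624 and 0.0568. At 4-fold or more, 16 genes were higher and 1040 lower. GNAQ had a log2 fold change of 0.11 (SE 0.051, adjusted p = 0.0615), which passed without either DMSO day 1 library (adjusted p = 0.0311 and 0.0312). GNA11 had 0.14 (adjusted p = 0.0110), not called without DMSO day 3 replicate 2 (adjusted p = 0.0658) or FR900359 day 3 replicate 1 (adjusted p = 0.0739). MITF had 0.22 (adjusted p = 1.32e-04), EZH2 0.46 (adjusted p = 3.91e-08), CCND1 -0.45 (adjusted p = 2.81e-09), MYC -0.01 (adjusted p = 0.871) and CDKN1B -0.52 (adjusted p = 4.89e-07). The median, the mean and the camera direction did not share a sign at day 3 for neural crest, Gq, prognosis, cholesterol, ribosome biogenesis and interferon genes.

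**Figure D3:**
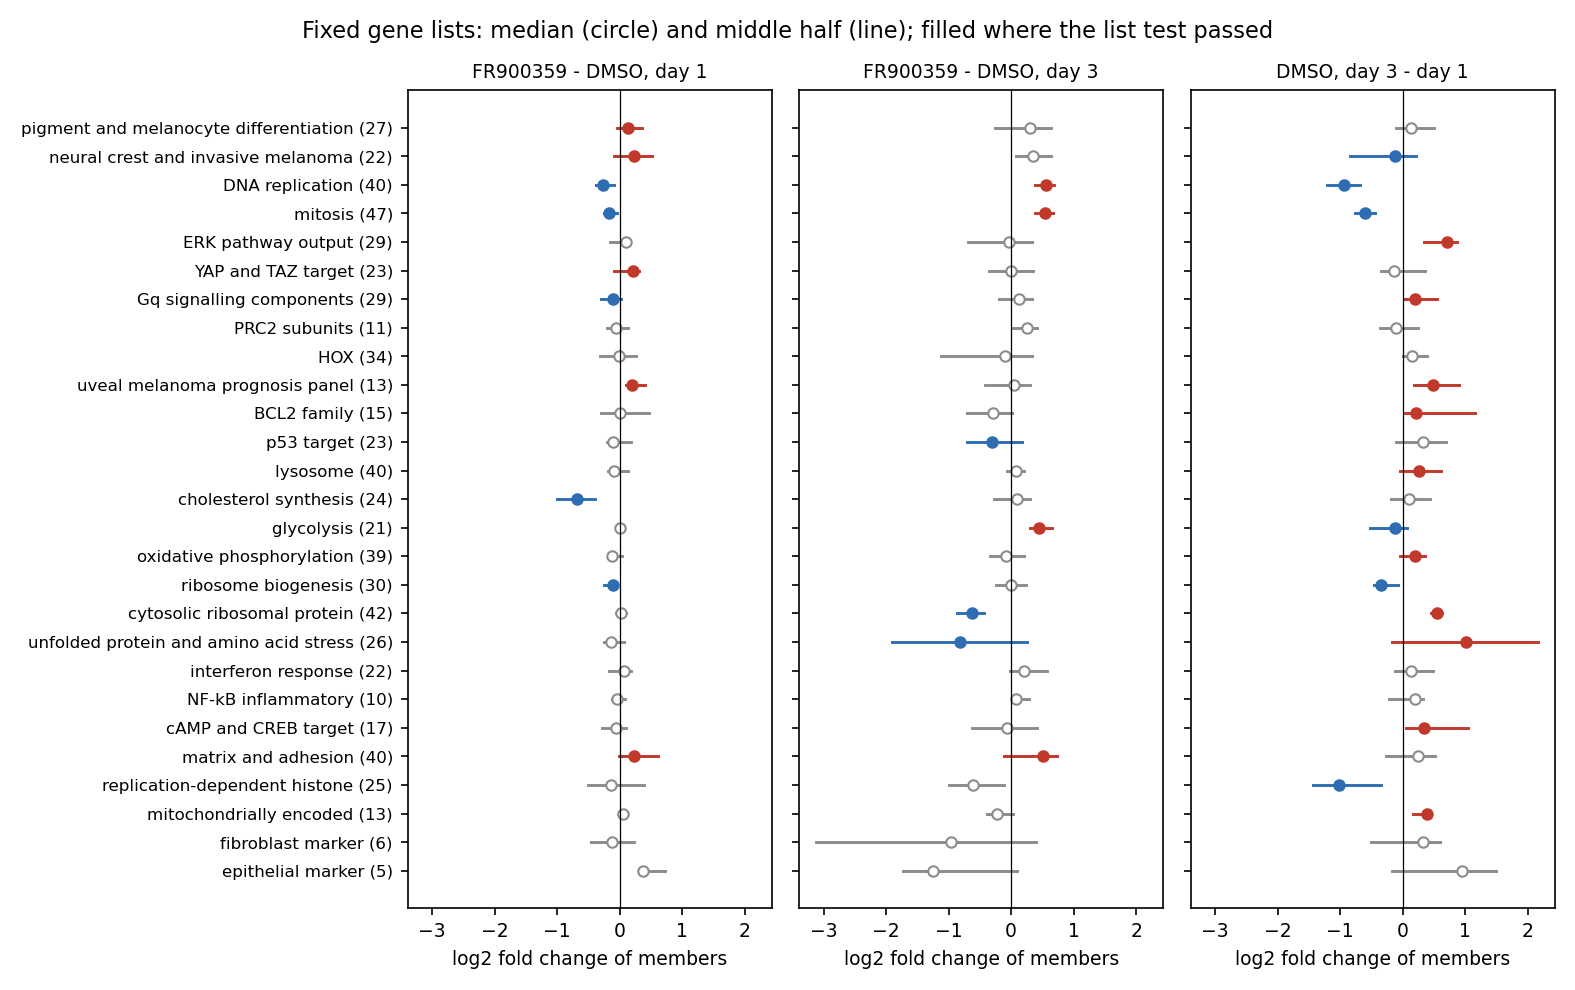
Log2 fold changes of the members of each tested gene list (number of tested genes in parentheses), with the median as a circle and the middle quartiles as a line, for FR900359 against DMSO at day 1 (left), day 3 (centre) and DMSO day 3 against day 1 (right). Filled circles passed the camera test (red up, blue down); DNA replication, mitosis and cholesterol synthesis lists moved differently at the days.

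The third comparison tested whether the effect of FR900359 differed between the days. INSIG1 and HMGCS1 of sterol synthesis had a higher effect at day 3, by 1.76 (SE 0.069, adjusted p = 1.35e-14) and 1.67 on the log2 scale, as had PTGES, a prostaglandin synthase, by 1.47, and POLQ, a DNA repair polymerase, by 1.45. SOD3 (-6.76, SE 0.13, adjusted p = 1.56e-19), DDR2 (-6.55), the protease inhibitor A2M (-6.23), ASB11 (-6.16) and TCN2, a cobalamin carrier (-6.12), had a far lower effect. In DMSO and FR900359, A2M was at 123 ± 4.02 and 149 ± 6.99 CPM at day 1, and at 432 ± 18.9 and 6.94 ± 0.172 CPM at day 3. ASB11 and TCN2 did not pass at day 1 (log2 fold changes 0.10 and 0.18, adjusted p = 0.469 and 0.321). In limma-trend the difference passed for 8258 of 17288 genes, 5039 with a higher and 3219 with a lower effect at day 3. Of these, 221 and 1623 differed by at least 2-fold. Scaling by total reads alone gave 3737 and 3955, and moved the median of all genes by -0.104.

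Of the 8258 genes, 1284 were called at both days the same way with a larger effect at day 3, 193 with a smaller. Another 1345 were called at both days in opposite directions, 4209 at day 3 alone, 981 at day 1 alone and 246 at neither day. Over the tested genes, the log2 fold changes of the days had a Pearson correlation of 0.329 and a Spearman correlation of 0.275, or 0.429 and 0.383 over the 9758 genes with a mean log2 CPM of at least 3. These are correlations across genes, which are not independent replicates. Between the days 1346 genes were up at both, where independent lists would share 767, and 1611 were down at both, where they would share 912. Another 410 were up at day 1 and down at day 3 (593 for independent lists), and 935 the reverse (1180). The days share no libraries.

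**Figure D4:**
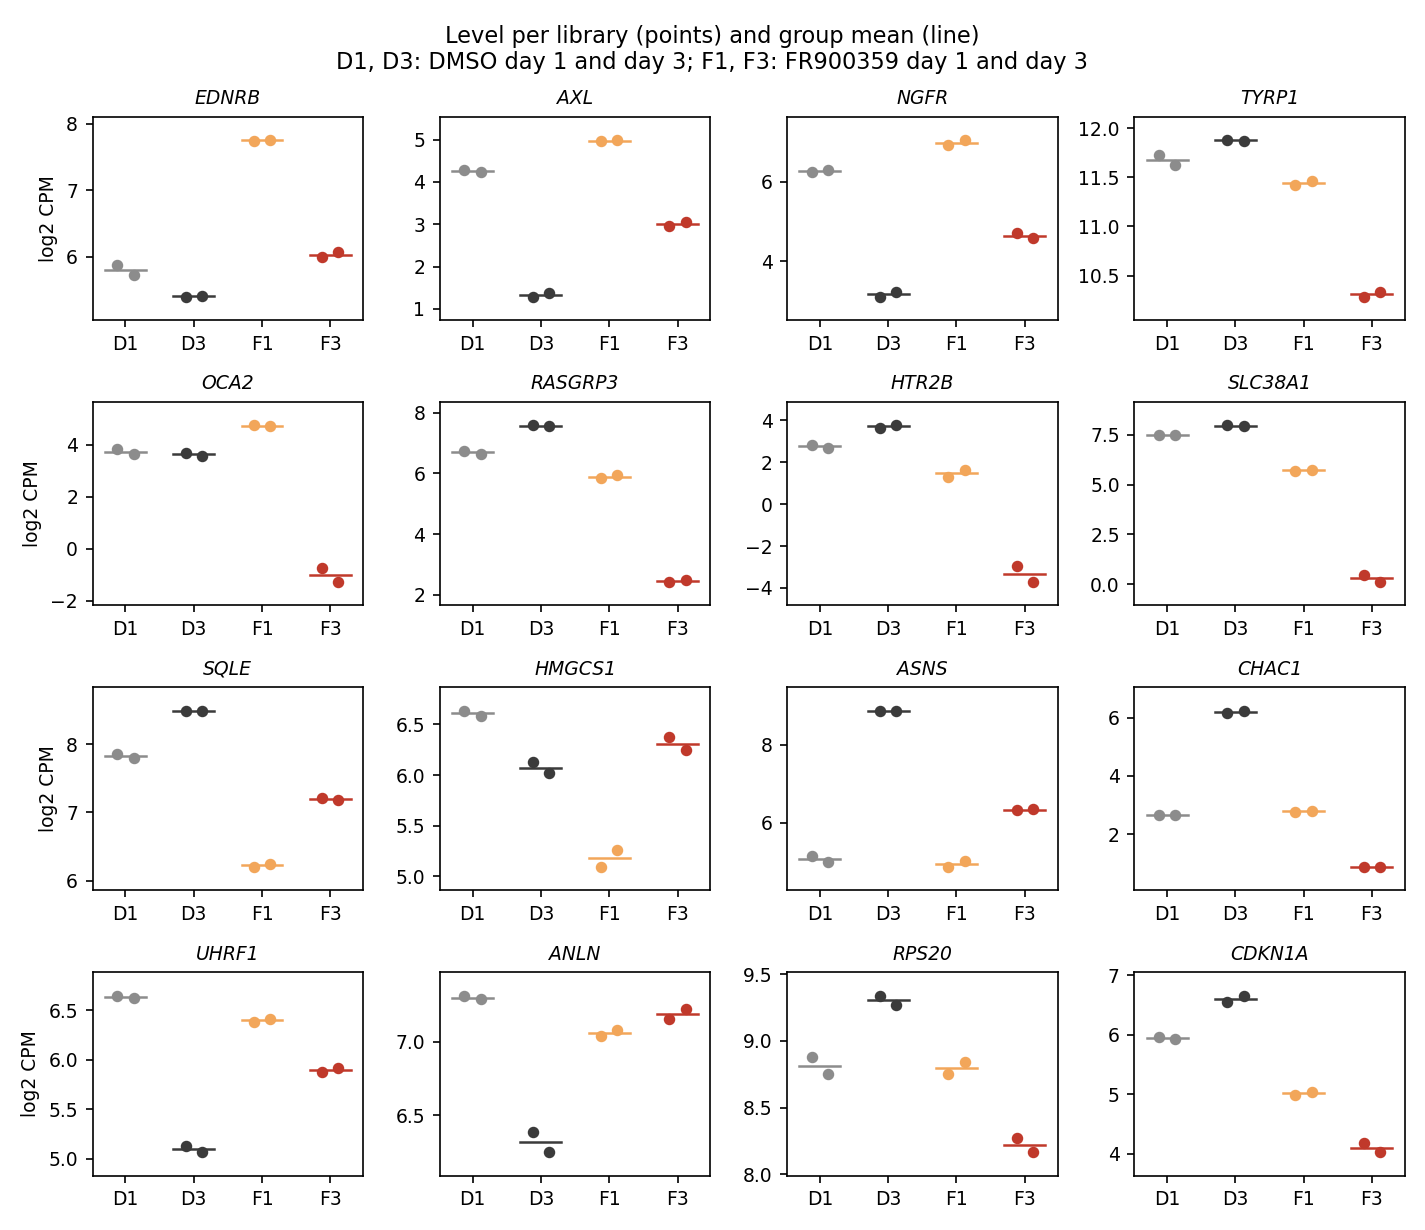
Log2 CPM of 16 named genes in each library (points) with group means (lines), for DMSO at day 1 and day 3 (D1, D3) and FR900359 at day 1 and day 3 (F1, F3); each panel has its own y axis. OCA2, HTR2B, SLC38A1 and RASGRP3 were lowest in F3, and UHRF1 and ANLN were lowest in D3.

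The last comparison followed the vehicle cultures from day 1 to day 3. Unfolded protein and amino acid stress genes rose in 17 of 26 and fell in 8, also adjusted over the list alone (median 1.01, camera adjusted p = 1.80e-04, and adjusted p = 0.465 with an estimated correlation). ASNS went from 33.5 ± 2.40 to 470 ± 0.108 CPM (log2 fold change 3.81, SE 0.057, adjusted p = 1.45e-20), CHAC1 from 6.28 ± 0.0599 to 73.6 ± 3.28 (3.55), and DDIT4 from 6.49 ± 0.369 to 67 ± 0.734 (3.37). Outside that list the peptide hormone gene ADM2 (3.82) and the stress regulator NUPR1 (3.09) rose. The inhibitors of differentiation ID1 and ID3 (-3.20 and -3.12), NGFR (-3.09), AXL (-2.93) and THBS1 (-2.71) fell. DNA replication genes were lower in 40 of 40 (median -0.94, camera adjusted p = 4.29e-26) and mitosis genes in 44 of 47 with 0 higher (median -0.60, camera adjusted p = 9.32e-21). Ribosomal protein genes were higher in 40 of 42 with 0 lower (median 0.55, camera adjusted p = 1.01e-14), with the same counts adjusted over the list alone. ERK output genes were higher in 23 of 29 and lower in 3 (23 and 3 adjusted over the list alone; median 0.71, camera adjusted p = 7.61e-07). With an estimated correlation these lists had adjusted p = 0.198, or adjusted p = 0.365 for ribosomal protein genes.

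11 further lists passed in DMSO over time by camera. Downward passed neural crest (10 down and 5 up of 22), glycolysis (12 and 3 of 21), ribosome biogenesis (22 and 2 of 30) and histone genes (14 and 0 of 25). Upward passed Gq components (17 up and 4 down of 29), the prognosis panel (11 and 2 of 13), the BCL2 family (9 and 3 of 15) and lysosome genes (24 and 8 of 40). Also upward were oxidative phosphorylation (23 and 5 of 39), cAMP targets (10 and 2 of 17) and mitochondrially encoded genes (10 and 1 of 13). Adjusted over the list alone the counts were 16 down and 1 up for histone, 25 up and 8 down for lysosome and 24 up and 6 down for oxidative phosphorylation genes, and the same for the other lists. None passed with an estimated correlation (adjusted p = 0.198 to 0.601). With upper-quartile and total-count scaling the calls ended for Gq components (adjusted p = 0.0586 and 0.0526) and oxidative phosphorylation genes (adjusted p = 0.147 and 0.1002). With upper-quartile scaling 12 Gq components were up and 6 down, 19 lysosome genes up and 13 down, and 14 oxidative phosphorylation genes up and 10 down. In limma-trend 9983 genes differed, 5532 higher and 4451 lower, of which 1192 and 958 by at least 2-fold. The split was 4131 and 6183 with upper-quartile scaling and 4322 and 5917 with total-count scaling, which moved the median of all genes by -0.142 and -0.121.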

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

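All tests that weigh an explanation in this part were chosen after the result was seen. What singled out each result here was a test of the difference between the days, (FR900359 - DMSO at day 3) - (FR900359 - DMSO at day 1). In limma-trend it passed for 8258 of 17288 genes, and by camera for 10 of the tested gene lists, none of them with an estimated correlation (adjusted p = 0.330 to 0.467). The median log2 difference was 0.74 for DNA replication genes, 0.68 for mitosis genes, 0.67 for cholesterol synthesis genes and 0.45 for glycolysis genes, all with a higher effect at day 3. The median was -2.06 for the 5 tested epithelial marker genes, which is the value of a single member, ESRP1. It was -0.84 for unfolded protein and amino acid stress genes and -0.65 for cytosolic ribosomal protein genes. BCL2 family genes had -0.29, mitochondrially encoded genes -0.23 and p53 target genes -0.10.

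The difference passed for 89 of the 93 genes named in the text, and is given here on the log2 scale. Most of these genes were picked from the same data for large changes, so this share says little about other genes. The effect was higher at day 3 by more than 1 for INSIG1 (1.76), HMGCS1 (1.67), PTGES (1.47), POLQ (1.45), AIM1 (1.38), MVD (1.29), MMP8 (1.28), SLC6A6 (1.2), PPARGC1A (1.13), ANLN (1.11), RNF182 (1.09), NTN1 (1.06) and UHRF1 (1.04). It was higher by less for NOV (1.00), AXL (0.96), NGFR (0.76), MYOF (0.73), ITGA4 (0.63), MYO5A (0.60), ID1 (0.55), SNAI2 (0.54), PKM (0.54) and ROBO1 (0.52), and for TNC (0.42), PHF19 (0.39), EZH2 (0.37), GNA11 (0.37), ID3 (0.34), THBS1 (0.32), SQLE (0.31) and MITF (0.27). Of these, THBS1 was not called without DMSO day 3 replicate 1 (adjusted p = 0.0527) or FR900359 day 1 replicate 1 (adjusted p = 0.0799).

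The effect was lower at day 3 for SPRY1 (-0.40), CDKN1B (-0.46), EPHA2 (-0.49), MT-ND1 (-0.49) and BCL2 (-0.55). Lower by more than 1 were NAV3 (-1.04), RPS20 (-1.07), PMAIP1 (-1.31), EDNRB (-1.32), TYRP1 (-1.33), STON1 (-1.43), BAIAP2L2 (-1.52), EGR1 (-1.53), PNPLA7 (-1.53), CDKN1A (-1.58), MXD4 (-1.86), NUPR1 (-1.89) and TEX15 (-1.97). Lower by more than 2 were ADM2 (-2.0), SESN2 (-2.01), ESRP1 (-2.06), AMOTL2 (-2.10), RPS28 (-2.17), HOXD1 (-2.24), LGI3 (-2.42), ASNS (-2.42), PKD1L2 (-2.47), HLX (-2.48) and BMF (-2.75). Lower by more than 3 were FBLN1 (-3.26), SLAMF7 (-3.40), NEFH (-3.45), DDIT4 (-3.74), SATB1 (-3.89), MYO15B (-3.98), ALDOC (-3.99), TNFRSF10B (-4.13), DYRK1B (-4.28), RASGRP3 (-4.31), ADRA2A (-4.37), WFDC1 (-4.41) and MTSS1 (-4.86). Lower by more than 5 were HOXB13 (-5.08), CDC42EP1 (-5.27), RSPO4 (-5.40), CHAC1 (-5.46), EMCN (-5.48), OCA2 (-5.65), HTR2B (-5.77), GBGT1 (-5.86), SLC38A1 (-5.89), MARC1 (-6.02), TCN2 (-6.12), ASB11 (-6.16), A2M (-6.23), DDR2 (-6.55), SOD3 (-6.76) and CD36 (-7.09). MARC1, a mitochondrial amidoxime reductase, and CD36, a fatty acid receptor, lie outside the rule for named genes and were chosen after their values were seen.

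At day 3, 73 genes stood at 5 CPM or more in both DMSO libraries and under 0.3 CPM in both FR900359 libraries, among them MARC1 (86.9 and 0.264 CPM on average) and CD36 (66.0 and 0.133 CPM). Other cells or a wrong label in the treated day 3 libraries alone would bring genes of their own, and 0 genes lay the other way. A loss of reads from genes of low abundance would lower their neighbours too, yet the 8107 other genes in the same range of DMSO levels had a median log2 fold change of 0.10, against -6.25 for the 73. Loss of a subset of cells that carried these transcripts cannot be told apart from silencing within cells, because the tables hold no single cells and the day 1 log2 fold changes of the 73, with an SD of 0.779 against a median SE of 0.228, may differ for either reason. At day 1, 46 of the 73 were already lower, 2 higher and 25 not called, which either reading allows.

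DNA replication and mitosis genes were lower with FR900359 at day 1 and higher at day 3, with a median log2 fold change of 0.55 over the 87 genes at day 3. The choice among the scalings tried does not account for it, since the lowest median over the other scalings was 0.49. Those scalings moved the day 3 median of all genes by only -0.0624 to 0.0568. An error shared by all of them could not be seen this way. The day 3 contrast goes with a fall in the vehicle cultures, whose density and medium were not tested. Between the days DMSO had a median of -0.94 for DNA replication and -0.60 for mitosis genes. FR900359 at day 3 lay at a median of -0.20 from DMSO at day 1, so as a set the genes did not rise above that level. Against DMSO at day 1 the DNA replication list was lower (median -0.45, camera adjusted p = 1.74e-07) and the mitosis list did not pass (median -0.07, camera adjusted p = 0.154), with adjusted p = 0.620 and 0.826 with an estimated correlation. Within treated cells from day 1 to day 3, DNA replication genes had 8 up and 26 down of 40 (median -0.22, camera adjusted p = 0.00118) and mitosis genes 23 up and 10 down of 47 (median 0.09, camera adjusted p = 0.717), with adjusted p = 0.552 and 0.945 with an estimated correlation.

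Ribosomal protein genes were lower with FR900359 at day 3, with a median log2 fold change of -0.63. Their transcripts are short (median 756 bases, against 1637 over tested genes), but the median was still -0.57 after removal of a trend with transcript length, which moved all genes by a median of 0.0537. The 2039 other protein-coding genes of like length had a median of 0.03, and the 3221 of like GC content 0.12 (quartiles -0.24 and 0.39). Both sets took genes at or above the mean level of the least abundant ribosomal protein gene. No upper limit was set, so abundance was not matched. Reads moved to pseudogene copies would raise these, yet their change was -0.951% of the 10540 CPM that the genes lost. Together the 42 genes held 20544 CPM in DMSO day 1, 21004 in FR900359 day 1, 30561 in DMSO day 3 and 20017 in FR900359 day 3, so the difference goes with a rise in the vehicle cultures, and a difference in growth state stays open and untested.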

How the results depend on the processing

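The fits with crossed experiment numbers and with a length or GC trend removed, and the list tests in DMSO under other scalings, were chosen after the data were seen. Counts of called genes at day 1, at day 3, for the difference between the days and in DMSO over time were 5814, 10265, 8258 and 9983. With an added 2-fold threshold they were 548, 2227, 1844 and 2150, fewer by construction. Under the other scalings, filters, limma-voom, groups and trends they stayed within 1.5 times. Leaving out 1 library in turn gave 3864 to 6217, 8959 to 10814, 7111 to 8759 and 8479 to 10028; the lowest day 1 count was without FR900359 day 1 replicate 1, and the cause was not tested. A lone library was assumed to vary like the other groups.

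With the replicate block the counts were 5662, 10167, 8158 and 9875, and 17 gene lists passed over both days as without it. Among named genes the replicate block ended the calls of MYC at day 1 and BCL2 in DMSO over time (adjusted p = 0.051), and changed no other call described in the text. With the day 1 experiment numbers of FR900359 crossed, 5742 genes were called at day 1.

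Of the 17 list calls, 10 at day 1 and 7 at day 3, 0 held with an estimated correlation, 0 of them at day 1 and 0 at day 3. With 4 residual degrees of freedom that version has little power. With fry, which does not compare a list with other genes, 35 lists passed over both days, 14 at day 1 and 21 at day 3. In DMSO over time 16 lists passed, and 16, 14 and 14 with RLE, upper-quartile and total-count scaling, all among the 16. Without 1 library, 17 to 21 lists passed over both days, 9 to 12 at day 1 and 7 to 9 at day 3. The correlation of the days across genes, 0.329, was 0.409 with the stricter filter, where fewer genes of low abundance were tested, and 0.284 to 0.326 without 1 library, lowest without DMSO day 1 replicate 2; the cause was not tested.

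In DMSO over time 2 named genes turned direction with upper-quartile scaling, MYO5A to -0.0047 (adjusted p = 0.93) and BCL2 to -0.016 (adjusted p = 0.807); that scaling moved the median of all genes by -0.142. Over the fits without 1 library, named genes kept direction and side of the threshold in 4756 of 4896 values, 102 lost and 38 gained a call. Of 612 values per scaling, 14 lost and 18 gained a call with total-count scaling. With upper-quartile scaling 9 lost and 10 gained a call, and with RLE scaling 5 and 8. With no low-count filter 8 lost a call. The planned tests on counts with the 2 count tools were not run, since the deposited unit is log2. The whole reads recovered from those values were tested with limma-voom in their place. Genes with few reads have larger standard errors.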

Other observations

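The treated cultures were also followed from day 1 to day 3, a contrast chosen after the data were seen and not repeated under other settings. None of the list calls held with an estimated correlation (adjusted p = 0.484 to 0.771). Cholesterol synthesis genes rose in 21 of 24 and fell in 2, also adjusted over the list alone, with a median log2 fold change of 0.80 (camera adjusted p = 4.23e-06). INSIG1 rose by 2.59 (SE 0.049), MVD by 1.16, HMGCS1 by 1.13 and SQLE by 0.97. Lysosome genes rose in 31 of 40 and fell in 5 (32 and 5 adjusted over the list alone; median 0.41, camera adjusted p = 5.40e-04). ERK output genes rose in 19 of 29 and fell in 4, also adjusted over the list alone (median 0.36, camera adjusted p = 0.00411). Among them SPRY1 rose by 1.28, while EGR1 had 0.12 (adjusted p = 0.109) and EPHA2 -0.03 (adjusted p = 0.760). Gq components (20 up and 6 down of 29, median 0.38) and cAMP and CREB targets (12 up and 3 down of 17, median 0.65) also passed upward, both with camera adjusted p = 0.0164 and the same counts adjusted over the list alone. RASGRP3 of the Gq list went the other way (-3.43). In DMSO over the same time, lists also passed upward for lysosome (24 of 40 up, median 0.27), ERK output (23 of 29, median 0.71), Gq (17 of 29, median 0.20) and cAMP genes (10 of 17, median 0.35). With upper-quartile scaling these medians were 0.13, 0.57, 0.06 and 0.20, and the Gq call ended (adjusted p = 0.0586), as with total-count scaling (adjusted p = 0.0526). Cholesterol synthesis genes in DMSO had 11 up and 7 down of 24 (median 0.10, camera adjusted p = 0.527), with a median of -0.05 with upper-quartile and -0.02 with total-count scaling.

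In the same contrast replication-dependent histone genes fell in 23 of 25 with 0 higher, also adjusted over the list alone (median -1.34, camera adjusted p = 1.95e-05). Most transcripts of these genes lack a poly(A) tail, so polyadenylated RNA holds a small part of them. Neural crest and invasive melanoma genes fell in 13 of 22 and rose in 5, also adjusted over the list alone (median -0.30, camera adjusted p = 0.00342), with AXL at -1.97 and NGFR at -2.33 but SNAI2 at 0.36. DNA replication genes fell in 26 of 40 and rose in 8 (26 and 9 adjusted over the list alone; median -0.22, camera adjusted p = 0.00118). Mitosis genes did not pass, with 23 up and 10 down of 47, also adjusted over the list alone (median 0.09, camera adjusted p = 0.717). Ribosome biogenesis (18 of 30 down, 7 up, median -0.18) and cytosolic ribosomal protein genes (21 of 42 down, 7 up, median -0.11) both had camera adjusted p = 0.00458 and the same counts adjusted over the list alone. In DMSO the median was -1.03 for histone, -0.12 for neural crest (-0.27 with upper-quartile scaling), -0.94 for DNA replication, -0.35 for ribosome biogenesis and 0.55 for ribosomal protein genes, the last moving the other way. In limma-trend 6697 genes were higher and 4620 lower in treated cells at day 3 than at day 1. The scaling factors were 1.08 and 1.07 in FR900359 day 1, and 0.921 and 0.923 in FR900359 day 3. This split and the counts of list members up and down were not repeated under other scalings. They may depend on the scaling, as the split in DMSO over time did.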
